A study of Mus musculus with 6 samples.

How the data were processed

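RNA of NIH3T3 cells was extracted with TRIzol, and 6 libraries were made with the Ovation SP Ultralow system and sequenced in pairs on a HiSeq2000, per the labels' protocols. The labels gave each library's siRNA, treatment and replicate number. The deposited values were whole-number counts per gene symbol for 24062 genes in each of 6 libraries, made by the authors and not normalised. The submitters' processing notes name TopHat2 2.1.0, HTSeq 0.6.1p1, DESeq2 and the mouse builds mm10 and GRCm38, without saying which made which file. The annotation and the strand setting of the counting were not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. Lines that name no gene were kept out of library sizes and tests. Of all reads in those lines and in genes, 32.9% to 38% were in genes, 33.8% to 37.5% in no annotated feature, and 27.9% to 31.3% not uniquely aligned. Members of gene families with near-identical copies are therefore undercounted or uncertain.

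Everything else was computed from these counts in R 4.3.3. Genes were kept by edgeR's filterByExpr by group with a count minimum of 10, which left 13185. Normalisation used TMM factors, and CPM values are counts scaled by them and by library size. Differences were tested with edgeR 4.0.16 (estimateDisp, glmQLFit with the robust option, glmQLFTest) on 4 group means over all 6 libraries, without a replicate block. Called genes had a Benjamini-Hochberg adjusted p under 0.05. This fit has 2 residual degrees of freedom, all from the IFN-beta groups, so the single untreated libraries are assumed to vary like those. Standard errors are the log2 difference over the square root of F.

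A total of 24 gene lists were written before the data were examined, as were the tests, the alternatives and the rule for named genes. One list, of genes encoded by the mitochondrial genome, had no member in the counts. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over lists. No list had an adjusted p under 0.05 with an estimated correlation in any of the 5 comparisons. That includes the interferon-stimulated list in the response with control siRNA, where 98 of 99 members were above 0 (median log2 difference 3.56). The correlation was estimated over 2 residual degrees of freedom and came to 0.89 for that list. A call lost with it therefore does not show that a list was unchanged, nor that it changed. Named genes were Supt6, the 10 highest and 10 lowest called genes at an average log2 CPM of 3 or more whose groups do not overlap, up to 4 members of every list with the smallest p, and a panel of 12 interferon-stimulated genes; some of these genes are not reported here. A gene at 0 counts was given a floor of 3 counts per library, and for genes at 1 to 3 untreated counts the ratio's interval came from the exact 95% Poisson interval of the untreated count. Intervals and floors cover counting error only. Log2 differences within a replicate number used log2 CPM with a prior count of 2. Gene positions came from GENCODE for GRCm38, and 23641 of the 24062 symbols (98.3%) were matched.

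The script was tested on simulated counts with 200 genes changed by known folds, drawn from the libraries' own means. Each library was drawn independently, without a difference shared by a replicate number. For SPT6 siRNA with IFN-beta, 18.8% of genes changed 2-fold, 85.7% of those changed 4-fold and 95.9% of those changed 8-fold were recovered among 12889 genes tested. In that simulation 10.1% of 109 calls were false when each gene kept its own estimated spread, above the nominal rate, and 5.17% when genes followed a smooth trend. For the response with control siRNA the false share was 19.5%, for the response with SPT6 siRNA 16.7%, for the untreated comparison 21.1% and for the difference of responses 22.4%, against 3.16%, 5.43%, 5.19% and 4.29% with the smooth trend. In these simulations the adjusted p-values therefore held the nominal error rate less well for genes of unusual spread.

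The same-group libraries with IFN-beta were not duplicates of each other (chi-square per degree of freedom 39.4 and 34.7 over genes). Alternatives covered size factors, library size only, DESeq2 1.42.0, limma-voom, edgeR without the robust option and its legacy form, 2 other count filters, a fold threshold, a replicate block, only the groups compared, and leaving out each IFN-beta library. A fit over 3 matched pairs and one without Rn45s were added after the data were seen. Their effect is given in the closing section.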

Results

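RNA was measured in NIH3T3 cells, an established mouse fibroblast line, to ask how the transcription elongation factor and histone chaperone SPT6 (gene symbol Supt6) bears on the response to interferon beta (IFN-beta). Cells received control siRNA or SPT6 siRNA for 48 h and were either untreated or given IFN-beta at 100 units/ml for 4 h. The sample titles place the untreated libraries at 0 h, and no 4 h library without IFN-beta is named. An effect of the 4 h themselves therefore cannot be told apart from one of IFN-beta. There were 6 libraries in 4 groups. Each untreated group had 1 library, called replicate 1, and each IFN-beta group had 2, called replicates 1 and 2. Counts assigned to genes came to 11968565 with control siRNA and 7935961 with SPT6 siRNA in the untreated pair. With IFN-beta they came to 13951889 and 17596498 with control siRNA and to 9861581 and 11174825 with SPT6 siRNA. The SPT6 siRNA library was thus the shallower one in each of the 3 pairs. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may in part be technical.

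The targeted gene was lower in each SPT6 siRNA library. Supt6 (chromosome 11, 78206746 to 78245987, minus strand, GRCm38; protein coding) stood at 175 CPM (read counts normalised to library size) with control siRNA and 101 CPM with SPT6 siRNA in the untreated pair. With IFN-beta it stood at 183 CPM ± 8.6 (SD, n = 2) with control siRNA and 98.4 CPM ± 14.1 (SD, n = 2) with SPT6 siRNA. The log2 difference with IFN-beta was -0.90 ± 0.18 (SE), a level 0.537 times that of control, and every SPT6 siRNA library lay below every control library. This difference was not called by the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.247), whereas DESeq2 called it (adjusted p = 0.0306).

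**Figure D1:**
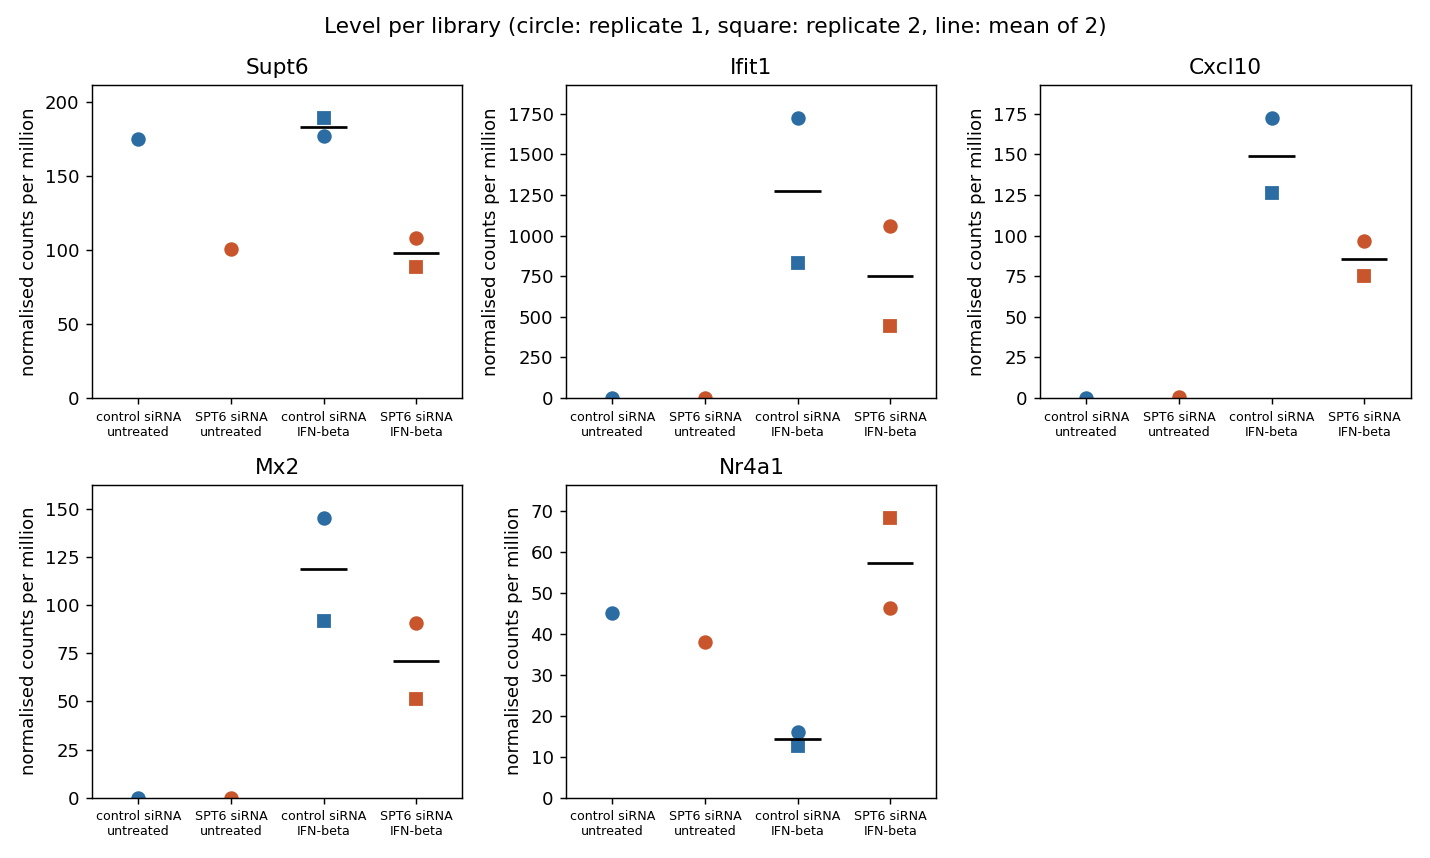
Normalised read counts in CPM (linear axes from 0) of 5 genes in each of the 6 libraries, by group; circles are replicate 1, squares replicate 2, and lines the mean of the 2 IFN-beta libraries. Supt6 lies between 88.4 and 108 CPM in the SPT6 siRNA libraries and between 175 and 189 CPM in the control libraries, and Nr4a1 is 16 and 12.6 CPM in the control IFN-beta libraries against 46.4 and 68.2 CPM with SPT6 siRNA.

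The first comparison asked which genes responded to IFN-beta with control siRNA. Antiviral and interferon-signalling genes rose from very low levels. Cxcl10, a chemokine gene (chromosome 5, 92346638 to 92348889), went from 3 counts untreated to 2281 and 2131 counts, a ratio of 605 (95% counting interval 207 to 2930). Mx2, of the Mx family of antiviral GTPases (chromosome 16, 97535308 to 97560900, annotated as a polymorphic pseudogene), went from 1 count to 1932 and 1548 counts, a ratio of 1440 (counting interval 259 to 57000). The immunity-related GTPase genes Irgm1 and Irgm2 rose by log2 5.68 ± 0.49 (SE) and 6.5 ± 0.60, and Irf7, a transcription factor of the interferon pathway, by 5.19 ± 0.55. Reads shared between close relatives such as Irgm1 and Irgm2, Apol9a and Apol9b, or Mx1 and Mx2 make the split between them uncertain.

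Of 13185 genes tested, 18 were called and all 18 were higher (edgeR quasi-likelihood test, adjusted p under 0.05). Others called were Rtp4 (log2 5.53 ± 0.53), AI607873 (4.26 ± 0.33), Ifi205 (4.07 ± 0.45), Apol9a (3.98 ± 0.41) and Apol9b, which went from 3 counts to 259 and 269. The chemokine gene Ccl2 rose from 25.6 CPM to 194 CPM ± 4.42 (SD, n = 2) and Irf9, a subunit of the interferon-activated transcription factor complex, by log2 3.22 ± 0.36. An unadjusted p under 0.05 was reached by 1086 genes. Other panel genes were far above the untreated library without passing the test over all genes. Ifit1 was at 2.14 CPM untreated and at 1720 and 833 CPM with IFN-beta (adjusted p = 0.119), and Isg15 at 4.19, 203 and 97.5 CPM (adjusted p = 0.248).

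Among 99 tested members of a fixed list of interferon-stimulated genes, 16 were called higher over all genes and 86 when adjusted over the list alone, and none was called lower. The median log2 difference was 3.56, or 3.46 with the 20 members at 3 or fewer untreated counts set to their counting ratio or bound. The camera set test with a preset correlation gave an adjusted p = 5.4e-212, and the call was lost with an estimated correlation (adjusted p = 0.47 with an estimated correlation). Adjusted over the list alone, 5 of 17 genes of the JAK-STAT pathway rose, among them Stat2 (log2 2.97 ± 0.37) and Usp18, a negative regulator of the pathway (6.26 ± 0.82). That list's camera call was likewise lost (adjusted p = 0.6 with an estimated correlation). Of 20 antigen presentation genes, 5 rose when adjusted over the list alone, including the peptide transporter gene Tap1 (log2 3.01 ± 0.52) and its regulator gene Nlrc5 (2.30 ± 0.40), and the list's camera call (adjusted p = 3.6e-11) was lost (adjusted p = 0.74 with an estimated correlation).

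Genes outside antiviral defence also differed. Among 49 extracellular matrix genes, 4 rose when adjusted over the list alone, including Ctgf (log2 2.57 ± 0.32) and Timp1 (1.41 ± 0.23). The median of that list was 0.08, at -0.01 when scaled by library size only, -0.02 without control IFN-beta replicate 1 and 0.19 without its replicate 2, and its adjusted p was 0.88 with an estimated correlation. Among 27 immediate early genes, 4 rose and 2 fell when adjusted over the list alone (adjusted p = 0.91 with an estimated correlation). Of 22 NF-kappaB, chemokine and cytokine genes, 2 rose and 1 fell when adjusted over the list alone, with a camera adjusted p = 0.026 (0.1 without control IFN-beta replicate 1; adjusted p = 0.6 with an estimated correlation). The nuclear receptor gene Nr4a1 (chromosome 15, 101254269 to 101274795) fell by 1.66 on the log2 scale ± 0.29 (SE). For 21 targets of serum response factor and actin signalling the median was 0.77 with none called, and the camera call (adjusted p = 1.3e-09) was lost with an estimated correlation (adjusted p = 0.47 with an estimated correlation).

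The count of 18 became 52 without SPT6 siRNA IFN-beta replicate 1 and 45 without its replicate 2, while DESeq2 called 204 and limma-voom 5. With each gene's own spread and no changed gene, 10 simulations of this comparison gave a median of 5 calls (2 to 12). With a spread that followed a smooth trend they gave a median of 0 (0 to 1). Some of the 18 may therefore be false, although 16 of them belong to the fixed interferon list. The simulations drew each library independently, without a difference shared by a replicate number, so their counts of false calls may not carry over. The only untreated library carries replicate number 1. Within that number the interferon list's median was 3.74, and replicate 2 against the same untreated library gave 3.

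The second comparison was the same response with SPT6 siRNA. Cxcl10 rose by log2 7.45 ± 0.50, the immune checkpoint ligand gene Cd274 by 4.46 ± 0.40, and the pyrin and HIN domain family genes AI607873 and Ifi203 by 4.19 ± 0.34 and 3.63 ± 0.29. Helz2 rose by 3.08 ± 0.26 and Trim25, a ubiquitin ligase gene of antiviral signalling, by 2.48 ± 0.24. Mx2 was at 0 counts untreated and 890 and 589 counts with IFN-beta, at least 197-fold higher (floor of 3 counts in the untreated library; adjusted p = 0.051). Ifit1 stood at 3 CPM untreated and 1060 and 444 CPM with IFN-beta (adjusted p = 0.204).

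These 6 genes were the whole of those called by the edgeR quasi-likelihood test, and 771 genes had an unadjusted p under 0.05. All 6 were among the 18 called with control siRNA, where 0.0082 would be shared by chance (two-sided Fisher's exact test, p = 2.55e-18). The 2 comparisons share no library, though each gene's spread is estimated from both. In the interferon list 5 members were called over all genes and 82 of 99 when adjusted over the list alone, with a median of 3.25 (3.06 with 21 low members at their ratio or bound; adjusted p = 0.7 with an estimated correlation). Adjusted over the list alone, 4 of 17 JAK-STAT genes rose (adjusted p = 0.7 with an estimated correlation) and 4 of 20 antigen presentation genes (adjusted p = 0.87 with an estimated correlation). The median of the replication-dependent histone genes was -0.43, with 45 of 46 below 0, none called, and a camera call (adjusted p = 1.7e-10) lost with an estimated correlation (adjusted p = 0.87 with an estimated correlation). The medians of immediate early genes (0.71), actin and serum response factor targets (0.38), cholesterol synthesis (-0.25) and ribosomal proteins (-0.20) had camera calls that were lost as well (adjusted p = 0.87, 0.7, 0.87 and 0.92 with an estimated correlation). Without SPT6 siRNA IFN-beta replicate 2 the immediate early median was 0.38 and that of cholesterol synthesis -0.12, the latter no longer called, and without its replicate 1 cholesterol synthesis was at -0.55. The ribosomal protein median was -0.01 in replicate 1 and -0.44 in replicate 2, each against the untreated library. The count of 6 became 14 without control IFN-beta replicate 1, 14 without its replicate 2, 9 without SPT6 siRNA IFN-beta replicate 1 and 25 without its replicate 2, while limma-voom called 0 and DESeq2 129. Simulations with no changed gene gave a median of 5 calls (2 to 11) for this comparison with each gene's own spread and 0 (0 to 1) with a smooth trend.

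The replicated comparison set SPT6 siRNA against control siRNA in IFN-beta treated cells. Interferon-stimulated genes lay lower with SPT6 siRNA within each replicate number, by values that did not pass the planned test for any gene. Ifit1 was at 1720 and 833 CPM with control siRNA and at 1060 and 444 CPM with SPT6 siRNA (log2 difference -0.76 ± 0.53, SE). Mx2 was at 145 and 91.9 against 90.7 and 51.2 CPM (-0.74 ± 0.34) and Cxcl10 at 172 and 126 against 96.7 and 74.8 CPM (-0.80 ± 0.23). For Ifit1 the groups overlapped, as SPT6 siRNA replicate 1 lay above control replicate 2. For Mx2 and Cxcl10 both SPT6 siRNA libraries lay below both control libraries. With 1 library left out at a time, the differences ran from -1.54 to -0.14 for Ifit1 and from -1.23 to -0.36 for Mx2, nearest 0 without control replicate 1.

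Over the 99 list members the median was -0.48 (quartiles -0.58 and -0.33), 93 were below 0 and the planned edgeR test called none, over all genes or adjusted over the list alone. The camera test with a preset correlation placed the list lower (adjusted p = 1.1e-08), and the call was lost with an estimated correlation (adjusted p = 0.66 with an estimated correlation). Within replicate number 1 the median was -0.41 and within number 2 it was -0.53. The same list was lower in number 2 than in number 1 by a median of -0.76 with control siRNA and -0.97 with SPT6 siRNA. The median therefore moved to 0.02 without control replicate 1, where the comparison is unbalanced over the numbers, and to -0.08 without SPT6 siRNA replicate 2, and the call was lost in both, while it was -0.83 without control replicate 2 and -1.05 without SPT6 siRNA replicate 1. Among the 18 genes called in the control response the median was -0.33, with 16 below 0 and 2 above. That set was chosen on the same control libraries, and when a set was chosen on control replicate 1 and measured without it, again unbalanced over the numbers, the median was -0.06.

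**Figure D2:**
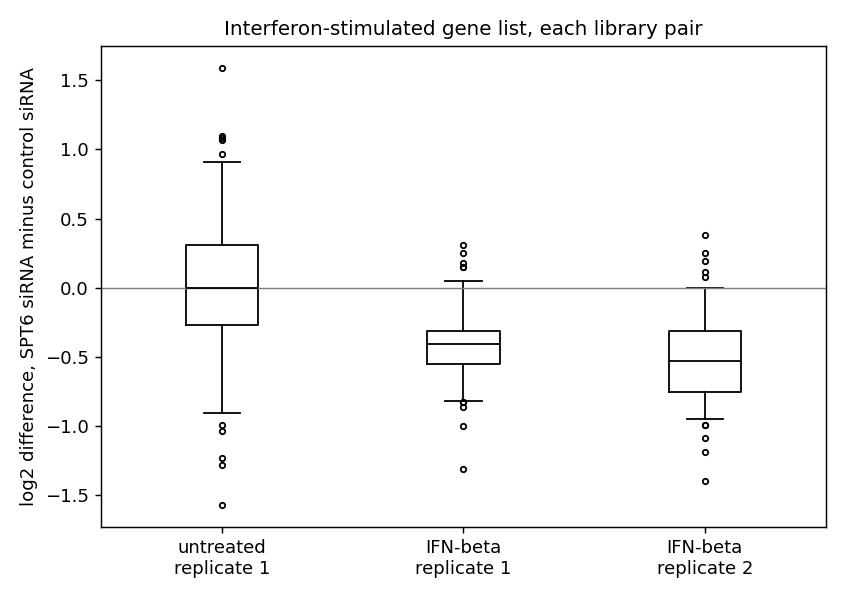
Log2 difference of SPT6 siRNA minus control siRNA for the 99 interferon-stimulated genes in each of the 3 library pairs; boxes span the quartiles, lines mark the median, whiskers the central 90 percent of genes and points the genes beyond. The medians are 0.00 untreated, -0.41 and -0.53 with IFN-beta.

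Genes of cell proliferation and the cytoskeleton also lay lower with SPT6 siRNA. Of 46 replication-dependent histone genes, 29 fell when adjusted over the list alone and all 46 were below 0, with a median of -0.65. Examples are Hist1h2bb (-0.94 ± 0.23), Hist1h4f (-0.70 ± 0.18) and Hist1h2af (-1.12 ± 0.24), whose reads may be shared with near-identical histone genes. The camera call (adjusted p = 2.4e-24) was lost with an estimated correlation (adjusted p = 0.65 with an estimated correlation). The 45 cell cycle genes had a median of -0.61, with 45 below 0 and none called (camera adjusted p = 5.1e-16; adjusted p = 0.65 with an estimated correlation). Their median was -0.33 and -0.82 within the 2 replicate numbers and -0.27 without control replicate 2. Among actin and serum response factor targets, Tgfb1i1 (-0.98 ± 0.21), Cnn2 (-0.87 ± 0.19) and the tropomyosin gene Tpm2 (-0.64 ± 0.16) fell when adjusted over the list alone (camera adjusted p = 6.8e-09; adjusted p = 0.65 with an estimated correlation). The remaining lists placed lower by camera were ribosomal proteins (median -0.37), cholesterol synthesis (-0.40) and extracellular matrix (-0.30), each with an adjusted p = 0.65 with an estimated correlation. Without SPT6 siRNA replicate 2 these medians were -0.18, -0.26 and -0.16. Without SPT6 siRNA replicate 1 ribosomal proteins were at -0.62 and cholesterol synthesis at -0.76. Without control replicate 1 cholesterol synthesis was at -0.26 and extracellular matrix at -0.08, the latter no longer called.

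Immediate early genes lay higher. Adjusted over the list alone, 5 of 27 immediate early genes rose, among them Nr4a1 (log2 2 ± 0.26), Nr4a2 (1.73 ± 0.31) and the transcription factor genes Atf3 (1.49 ± 0.37) and Maff (1.21 ± 0.32). The list's median was 0.47, with adjusted p = 0.65 with an estimated correlation. It was 0.28 without control replicate 1, 0.74 without control replicate 2 and 0.16 without SPT6 siRNA replicate 2. Adjusted over their own lists alone, Dnajb9, a chaperone gene of the endoplasmic reticulum, rose by 1.17 ± 0.21 and Nfkbia, an inhibitor of NF-kappaB, by 0.86 ± 0.17. Their lists did not lie higher, as the unfolded protein response list had a median of -0.13 with 19 of 26 members below 0, and the NF-kappaB, chemokine and cytokine list one of -0.09 with 12 of 22 below 0. The p53 target list had a median of 0.29 and none called (camera adjusted p = 0.034, 0.1 without control replicate 1 and 0.064 without SPT6 siRNA replicate 1; adjusted p = 0.65 with an estimated correlation), with Rrm2b at 0.81 ± 0.19 and Cdkn1a at 0.48 ± 0.18. The macrophage list, fixed to look for other cell types, had a median of 0.74 over 6 tested genes (adjusted p = 0.65 with an estimated correlation). Its member Cd68 was at 2.71 and 2.2 CPM with control siRNA and 7.75 and 9.92 CPM with SPT6 siRNA and rose when adjusted over the list alone. Vwf of the endothelial list (log2 2.32 ± 0.65) and Ovol1 of the epithelial list (6.39 ± 1.93) rose likewise, over only 3 and 2 tested genes. Over all genes the edgeR test gave them adjusted p = 0.339 and 0.36. Vwf differed by 0.93 and 3.02 within the 2 replicate numbers. Ovol1 was at 0 counts in both control libraries and at 2 and 17 counts with SPT6 siRNA. The endothelial list had a median of -0.10 over 3 tested genes, and no member of the other marker lists was called.

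Over all 13185 genes edgeR called 0 in this comparison (smallest adjusted p = 0.122), while 1538 had an unadjusted p under 0.05, 970 higher and 568 lower. DESeq2 called 62 genes and limma-voom 0. These fits leave the replicate number out of the model. With that number as a block edgeR called many more genes, as given in the closing section. The share of counts from Rn45s, the ribosomal RNA precursor, was 1.09% and 1.29% with control siRNA and 1.04% and 2.39% with SPT6 siRNA.

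**Figure D3:**
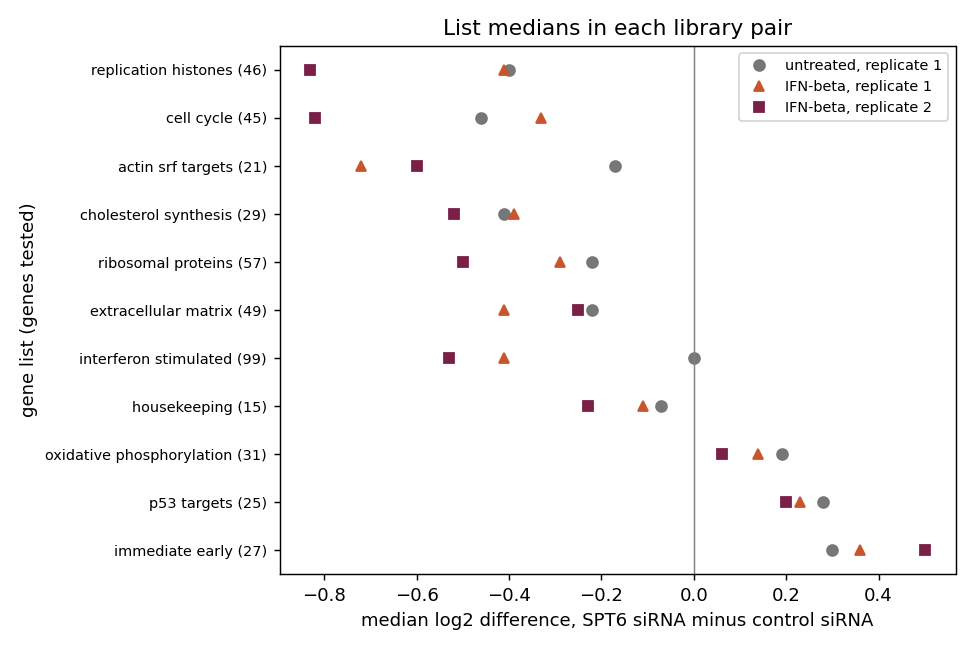
Median log2 difference of SPT6 siRNA minus control siRNA for 11 gene lists in each of the 3 library pairs, with the number of genes tested in brackets. The histone list lies at -0.40, -0.41 and -0.83 and the immediate early list at 0.30, 0.36 and 0.50, while the interferon list lies at 0.00 without IFN-beta.

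In untreated cells the SPT6 siRNA comparison rested on 1 library against 1 and had no replicate check. Cell cycle genes had a median log2 difference of -0.46 and replication-dependent histone genes of -0.40. Both lay at the 0 percentile of 10000 random lists matched on mean expression, which describes these 2 libraries. So did cholesterol synthesis genes, and ribosomal proteins lay at the 0.02 percentile, so such a place was not particular to proliferation genes. The genes of a list can vary together, unlike genes drawn at random, which makes extreme percentiles easier to reach. The proliferation marker gene Mki67 was at 761 CPM with control siRNA and 450 CPM with SPT6 siRNA, and Hist1h1e at 381 and 240 CPM. Immediate early genes had a median of 0.31, with Maff at 6.41 and 22.1 CPM and Dusp4 at 5.92 and 26.1 CPM. The p53 targets had a median of 0.29, with Cdkn1a at 48.9 and 75.5 CPM. The interferon list had a median of 0.00, with 48 members above 0 and 48 below, at the 76.2 percentile of matched random lists. With the spread borrowed from the IFN-beta groups, edgeR called 0 genes, 343 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom 0.

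The last comparison asked whether the IFN-beta response itself differed between the siRNAs. No gene was called by edgeR (smallest adjusted p = 1), 50 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Nr4a1 went from 45.2 CPM to 16 and 12.6 CPM with control siRNA and from 37.9 CPM to 46.4 and 68.2 CPM with SPT6 siRNA. This difference of responses was log2 2.25 ± 0.43 (SE; adjusted p = 1 over all genes, 0.0398 when adjusted over the list alone). The interferon list had a median difference of -0.45, with 82 of 99 members below 0 and none called. Its camera call (adjusted p = 1.5e-08) was lost with an estimated correlation (adjusted p = 0.77 with an estimated correlation), and the median moved to -0.02 without control IFN-beta replicate 1 and to -0.14 without SPT6 siRNA IFN-beta replicate 2, against -0.76 without control replicate 2 and -1 without SPT6 siRNA replicate 1. For Ccl2 the difference was -0.88 ± 0.28 (adjusted p = 1). The actin and serum response factor targets had a median of -0.39 and none called (camera adjusted p = 1.6e-06; adjusted p = 0.77 with an estimated correlation). That median was -0.24 and no longer called without control replicate 1, -0.62 without control replicate 2 and -0.61 without SPT6 siRNA replicate 1.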

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

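The tests of 1 replicate number alone, of the level before IFN-beta and of S-phase genes were chosen after the results they bear on had been seen.

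Among 77 named genes at log2 CPM 3 or more, 12 (15.6%) went one way in both control IFN-beta libraries and the other way in both SPT6 siRNA ones, against 6.69% of all 9814 genes at that level. The opposite directions themselves were not tested. The difference of responses had an adjusted p of 1 over all genes for each, Nr4a1 passed when adjusted over the list alone (0.0398), and named genes had been picked for small p. Nr4a1 differed by log2 2.25 ± 0.43 (SE) and Nr4a2 by 2.03 ± 0.53, both lower after IFN-beta with control siRNA and higher with SPT6 siRNA, and Vegfa by 0.59 ± 0.27. The other 9 responded in the opposite sense. They were Relb (-0.65), Sdf2l1 (-0.59), Pfkl (-0.52), Rplp2 (-0.44), Nelfcd (-0.40), Egln1 (-0.39), Serpinh1 (-0.38), Tubb5 (-0.32) and Uqcrq (-0.24). Both responses with 1 siRNA share a single untreated library, so an error in it moves both the same way.

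Reads in no annotated feature, which no comparison uses, made up 35.9% and 37.5% of reads with SPT6 siRNA and IFN-beta, against 34.4% and 33.8% with control siRNA and IFN-beta. In the untreated pair the order was the other way round, 35.3% with SPT6 siRNA and 37.1% with control siRNA.

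The interferon list was lower with SPT6 siRNA in IFN-beta treated cells by a median of -0.48. Its expression level, transcript length and GC content do not account for this, since the median lay at the 0 percentile of 10000 matched lists, whose central 90 percent ran from -0.10 to 0.03. A single replicate number does not account for it either, as the weaker of the within-number medians was -0.41. A lower level before IFN-beta stays open, since the ratio of the medians (0) rests on 1 untreated library per siRNA, and of the 71 members at 1 CPM or more 33 were higher and 38 lower there. A weaker interferon response after SPT6 siRNA stays open as a hypothesis. So does chance variation of the treatment between dishes, as only 2 pairs with IFN-beta were measured. Between replicate numbers the list differed by -0.76 with control siRNA and -0.97 with SPT6 siRNA. That shift was largely shared by the siRNAs, so it does not measure how far their difference varies. Within the numbers that difference was -0.41 and -0.53.

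The replication histone list was lower with SPT6 siRNA by a median of -0.65. Its expression level, length and GC content gave the 0 percentile of matched lists (central 90 percent -0.15 to 0.04). A lower yield of RNA without a poly(A) tail would lower other such RNAs, and with IFN-beta their median over 11 genes was 0.30. It was 0.08 within replicate number 1 and 0.41 within number 2. These 11 genes include Rn45s, whose share of counts was largest in SPT6 siRNA replicate 2 (2.39%). In the untreated pair their median was -0.14, beside -0.40 for the histone list, so there a lower yield was not excluded. Fewer cells in S phase may account for part of it, as 20 S-phase genes other than histones had a median of -0.56, 19 of them below 0. A direct effect on histone transcription was not tested.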

How the results depend on the processing

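The fit over 3 matched pairs and the one without Rn45s were chosen after seeing the data. The 18, 6, 0, 0 and 0 calls (response with control siRNA, with SPT6 siRNA, SPT6 siRNA effect with IFN-beta, untreated, difference of responses) became 204, 129, 62, 2 and 0 with DESeq2 and 77, 46, 66 and 1 in the first 4 with no filter on low counts. The first 2 became 5 and 0 with limma-voom, 11 and 3 with edgeR not robust, and 34 and 14 with only the groups compared. The second became 12 with library size only and 11 without Rn45s. With each library left out in turn they ranged from 16 to 52 and from 9 to 25, and the other 3 stayed at 0. The cause was not tested, except that only the groups compared means fewer samples.

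With the replicate number as a block (replicate block) the 5 counts were 957, 545, 2638, 308 and 4, and of the 99 interferon list members 61 were called lower with SPT6 siRNA and IFN-beta, where the planned fit called 0. The deviations of same-numbered libraries from their group means correlated at 0.56 across genes. The replicate numbers thus differed in part alike with both siRNAs, and the fit without the block counts that shared difference as spread. Its 0 calls for SPT6 siRNA with IFN-beta therefore do not show that no gene differed. The labels do not say what a number means, and 2 pairs do not establish pairing. The replicate block over 3 matched pairs estimated 1 common SPT6 siRNA effect over the untreated pair and both IFN-beta pairs. Its values are therefore not those of the effect with IFN-beta alone. It called 3245 genes, 1571 higher and 1674 lower (56 list members lower and 1 higher), and the highest of the other 3 sign flips of the pairs called 0. Only 1 of 4 flips gave as many, and 4 are too few for a share under 0.05. Supt6 was -0.90 with DESeq2 (adjusted p = 0.0306), -0.90 with the replicate block (5.61e-08) and -0.86 with 3 matched pairs (5.73e-06), each now past the threshold, and -1.06 to -0.76 with libraries left out.

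The interferon list medians 3.56, 3.25, -0.48 and -0.45 lost their call with an estimated correlation and with fry, which does not compare the list with other genes. With libraries left out they ranged from 3.20 to 3.95, 2.59 to 3.59, -1.05 to 0.02 and -1 to -0.02. The median of the induced genes (-0.33) was -0.24 with library size only, -0.28 with limma-voom, -0.30 with edgeR not robust, -0.36 with no filter, -0.27 when chosen in the SPT6 siRNA arm and -0.06 when chosen on control replicate 1 and measured without it. With libraries left out it ran from -0.94 to -0.12.

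Values that reversed were the interferon list for SPT6 siRNA with IFN-beta, at 0.02 without control replicate 1, and the extracellular matrix list in the control response, at -0.01 with library size only and -0.02 to 0.19 with libraries left out. The SPT6 siRNA effect with IFN-beta ran from -1.78 to 0.12 for Ifit3, -1.34 to 0.06 for Isg15, -1.55 to 0.17 for Oasl2 and -1.05 to 0.11 for Usp18. In the difference of responses the ribosomal protein list ran from -0.42 to 0.05 and the antigen presentation list from -0.59 to 0.07. Leaving out 1 library unbalances the replicate numbers by construction. Over all values and alternatives, 1638 kept direction and side of the threshold, or gave a similar count, 119 came to pass it, 52 no longer did, 37 values or counts without a test moved and 10 reversed. Of the 1638, 1494 belong to single genes or lists, including genes that did not pass the threshold in the planned fit. In the planned fit, whose spread takes in the difference between replicate numbers, 2-fold changes were mostly missed in simulation (18.8% recovered for SPT6 siRNA with IFN-beta). No simulation with a replicate block, or with a difference shared by a replicate number, was run.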

Other observations

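The test of depth or ribosomal RNA as a source of the replicate difference, and the reading of the gene span tests as undecided, were chosen after those results had been seen, and the genes named here were chosen after their values were seen.

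The replicate numbers differed in genes outside the fixed lists. Igf2, a growth factor gene, was at 82.1, 84.8, 80.9 and 70.4 CPM in the 4 libraries numbered 1 and at 1.19 and 1.22 CPM in those numbered 2. Lbp was at 13 to 19.1 CPM in the former and at 1.37 and 1.39 CPM in the latter, while Plxna4 was at 4.93 to 12.4 CPM and at 47.5 and 56.8 CPM. These differences were of one direction with either siRNA, by log2 -5.90 and -5.67 for Igf2. The interferon list was lower in number 2 by -0.97 with SPT6 siRNA and -0.76 with control siRNA. A difference present with both siRNAs cannot come from depth or ribosomal RNA of 1 library alone. Both number 2 libraries, however, were deeper than the number 1 library with the same siRNA and IFN-beta. Their Rn45s share was also larger, 1.29% against 1.09% with control siRNA and 2.39% against 1.04% with SPT6 siRNA. A shared difference in depth or ribosomal RNA that scaled all genes alike would not move lists in opposite directions. The immediate early list was higher in number 2, by 0.50 with control siRNA and 0.55 with SPT6 siRNA, where the interferon list was lower. For these lists the values argue against such a common scaling. Other effects of depth or ribosomal RNA shared by number 2 were not excluded. A different culture or passage behind each number may be involved and no biological explanation was tested. No untreated library carries number 2.

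Some genes stood apart between the siRNAs in each of the 3 pairs. Polr2l, encoding a small RNA polymerase subunit, was at 28.7, 39.4 and 44.3 CPM with control siRNA and at 136, 130 and 155 CPM with SPT6 siRNA. Cd93, a transmembrane receptor gene, was at 11.3, 12 and 8.84 CPM and at 41.5, 50.3 and 56 CPM. Neither passed the planned test with IFN-beta (log2 1.77 ± 0.18, adjusted p = 0.124, and 2.35 ± 0.23, adjusted p = 0.122). The edgeR fit over 3 matched pairs, chosen after the data were seen, called both. It gave 1.92 ± 0.11 for Polr2l (adjusted p = 3.4e-10) and 2.21 ± 0.15 for Cd93 (adjusted p = 2.25e-09). Across 13185 genes the SPT6 siRNA differences of pairs that share no library correlated at Pearson r = 0.50, 0.53 and 0.60, and 54.2% had one sign in all 3 pairs where independent signs give 25%. Genes are not independent replicates, and SPT6 siRNA libraries were the shallower in each pair.

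Within the interferon list, a larger induction in a control library went with a lower SPT6 siRNA difference in the other replicate number (Spearman rho -0.35 and -0.51 across 99 genes, with no library in common). Genes are again not independent.

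A lower SPT6 siRNA difference in longer genes, as a defect in elongation could give, was seen in the untreated pair and not in the IFN-beta pairs. Over 9751 genes the Spearman correlation with gene span was -0.16 untreated (-0.08 given transcript length; medians 0.03 in the shortest and -0.09 in the longest part of the genes when split into 4) and 0.03 and 0.06 with IFN-beta (0.06 and -0.01 given transcript length). The values for transcript length (mean partial correlation -0.01) and for a trend between control libraries (0.04) met the criteria set in advance for these explanations. The latter did so by size only, as its sign was opposite to the -0.16 of the untreated pair. With the pattern in only 1 of 3 pairs these values decide nothing.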
